A study of Mus musculus with 2 samples.

How the data were processed

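Trimethylation of histone H3 at lysine 36 (H3K36me3), a mark laid down over the bodies of transcribed genes, was profiled by chromatin immunoprecipitation and sequencing in mouse embryonic heart at day 10.5 of development. The series held 1 group of 2 biological replicates. Each replicate was a pool of hearts from male and female embryos of strain B6NCrl, 69 embryos in replicate 1 and 51 in replicate 2, with fragments selected at 300 to 500 bp, per the labels. The values analysed were 4 deposited peak lists. One list was called on each replicate alone and another on the pooled alignments of both, and the last was the list of replicated peaks derived from these 3, per the readme text deposited with the samples. The assembly was mm10, per the same text. The aligner, the peak caller, its version and its settings were not given in the sources used here. The list of replicate 1 was made from its alignments and 1 further file, and that of replicate 2 from its alignments and 2 further files. What these further files held was not given in the sources used here.

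Each deposited peak carried a signal value, the authors' enrichment score of that peak, which was used only to describe peaks within a list. Each deposited peak also carried a −log10 p-value and a −log10 q-value set by the authors. The −log10 p was never below 2 in any list, and peaks with a −log10 q under 2 stood in every list. The number of sequenced reads was not given, so the depth of either library is unknown, and no counting interval could be attached to a value. A region without a peak is therefore described as having no peak in these lists, not as lacking the mark.

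Gene models were taken from GENCODE mouse release M21, which uses the same assembly, and no peak on a chromosome ran past its end. Chromosomes 1 to 19, X and Y were used. Of 21938 protein-coding genes, 21911 were left after 1 gene was kept per symbol. Overlapping peaks were merged, and the percent of each gene body (annotated start to end) covered by peaks was computed. A gene was called marked when at least 10% of its body was covered. The replicated list gave the main value, and each replicate's own list gave the values from which means and SDs over 2 replicates were taken. Peaks carry no strand, so coverage of a gene that overlaps another cannot be assigned to either, and 4704 of the genes overlapped another protein-coding gene.

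The replicates were compared by the percent of peaks with at least 50% of their length covered by the other replicate's peaks and by the Jaccard index of covered bases. Chance values came from 100 circular shifts of a list within each chromosome, for which the smallest p is 0.0099. Bases of peaks were assigned in order to the region within 1 kb of a protein-coding gene start, to exons, to introns, to other annotated genes and to sequence outside genes. Position along the gene was measured in 10 equal bins from start to end of marked genes of 10 kb or more. Domains were replicated peaks merged over gaps of up to 5 kb.

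A set of 29 gene lists was tested with two-sided Fisher's exact tests of marked members against all other protein-coding genes, with Benjamini-Hochberg adjustment over the 29 lists and a threshold of 0.05. A small constant was added to each count before the log2 odds ratio was taken. For lists with none or all of their members marked, its size therefore depends on list size. Beside each test stood the median coverage of the list among 10000 random lists matched on gene length in 20 bins. For chromosome X, marked genes were compared with those of the autosomes by a two-sided Fisher's exact test. Genes are not independent replicates, so these tests describe these libraries. With 1 group of 2 samples no test between samples could be made.

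The genes named were fixed by rule before the data were examined. They were a set of 20 heart, other-tissue and methyltransferase genes (Tnnt2, Myh6, Myh7, Actc1, Ttn, Ryr2, Nkx2-5, Gata4, Tbx5, Tbx20, Hand2, Isl1, Pecam1, Nfatc1, Wt1, Hbb-bh1, Myod1, Alb, Neurod1 and Setd2), the 3 members with the largest and the 2 with the smallest coverage of each list described (ties by symbol), the 10 protein-coding genes of 10 kb or more with the largest coverage, the protein-coding genes in the 10 longest domains, and the 10 longest domains without an annotated gene. The lists, the tests and the alternatives were also fixed before the data were examined, except where stated.

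Alternatives covered the pooled list, stricter limits on q (−log10 q of at least 2 and 5), each replicate alone, marking limits of 5% and 20%, the first 1 kb of genes left out, genes under 2 kb left out, overlapping genes left out, other overlap rules, and merging gaps of 1 and 10 kb. The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6. Coverage was tested on simulated intervals against a count per base, and 0 of 2000 queries differed. The list test was tested on simulated marks over the 21911 genes. It called 98.5% of lists of 20 genes in which 90% were marked and 52% of those in which 70% were marked. For lists of 20 genes marked below the background share, it called 84% at a share of 10% but 41.5% at 20%. A list of that size with 20% marked was therefore missed more often than called. The test called 2.5% of lists of 20 genes marked at the background share of 41%. The simulated marks did not depend on gene length, whereas the real share of marked genes did. This rate therefore need not hold for lists of mostly short or long genes.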

Results

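The data collected were peaks of H3K36me3 in heart tissue of mouse embryos at day 10.5, in 2 biological replicates of pooled hearts. At this stage the heart is a looped, beating tube of muscle lined by endocardium. The list of replicate 1 held 283413 peaks over 63.3 Mb, and that of replicate 2 held 388720 peaks over 118 Mb. Median peak lengths in these lists were 139 bp for replicate 1 and 149 bp for replicate 2. The pooled list held 232987 peaks over 164 Mb, with a median length of 330 bp. The replicated list held 137455 peaks over 143 Mb, 5.23% of the chromosomes, with a median length of 579 bp. All 137455 of its peaks stood in the pooled list with the same coordinates and signal, and 20.8% of them had at least 50% of their length covered by peaks of replicate 1, against 70.9% for replicate 2. Read numbers were not given, so depth is unknown, and replicate 1 covered less sequence than replicate 2 on each autosome and on X.

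The contractile genes Ttn, Myh6, Myh7 and Tnnt2 of heart muscle were covered along most of their length in the replicated list, and less in replicate 1 alone (42.7%, 39.3%, 25.9% and 39.0%). Ttn, the gene of the giant sarcomere protein titin (chromosome 2, 76703980 to 76982547), was covered over 87.8% of its body by replicated peaks, with 60.5% ± 25.2 (SD, n = 2) across the replicates' own lists. Myh6 and Myh7, the neighbouring heavy-chain myosin genes on chromosome 14, were covered over 82.0% (54.3% ± 21.2, SD, n = 2) and 80.2% (44.4% ± 26.1, SD, n = 2). Tnnt2, the cardiac troponin T gene (chromosome 1, 135836354 to 135852260), stood at 79.2% (54.9% ± 22.5, SD, n = 2). Actc1, cardiac actin, stood at 27.0%, and Ryr2, the calcium release channel, at 30.3%; both were under the 10% limit in replicate 1 alone, at 8.58% and 8.21%.

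The cardiac transcription factor genes Tbx20 and Tbx5 were covered over 70.2% and 69.8% of their bodies, Hand2 over 53.6%, Gata4 over 33.2% and Nkx2-5 over 27.5%. In replicate 1 these 5 genes had 25.5%, 30.6%, 14.8%, 14.5% and 16.1%. Isl1, a gene of the second heart field progenitors, was covered over 1.42%, and Wt1, an epicardial gene, over 4.05%. The endothelial gene Pecam1 reached 8.89% and the endocardial gene Nfatc1 12.8%, with 2.04% and 2.84% in replicate 1. No peak of any list lay over Hbb-bh1 (embryonic globin), Myod1 (skeletal muscle), Alb (liver albumin) or Neurod1 (neurons). Setd2, the H3K36 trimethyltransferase gene, was covered over 65.9% (30.3% in replicate 1).

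**Figure D1:**
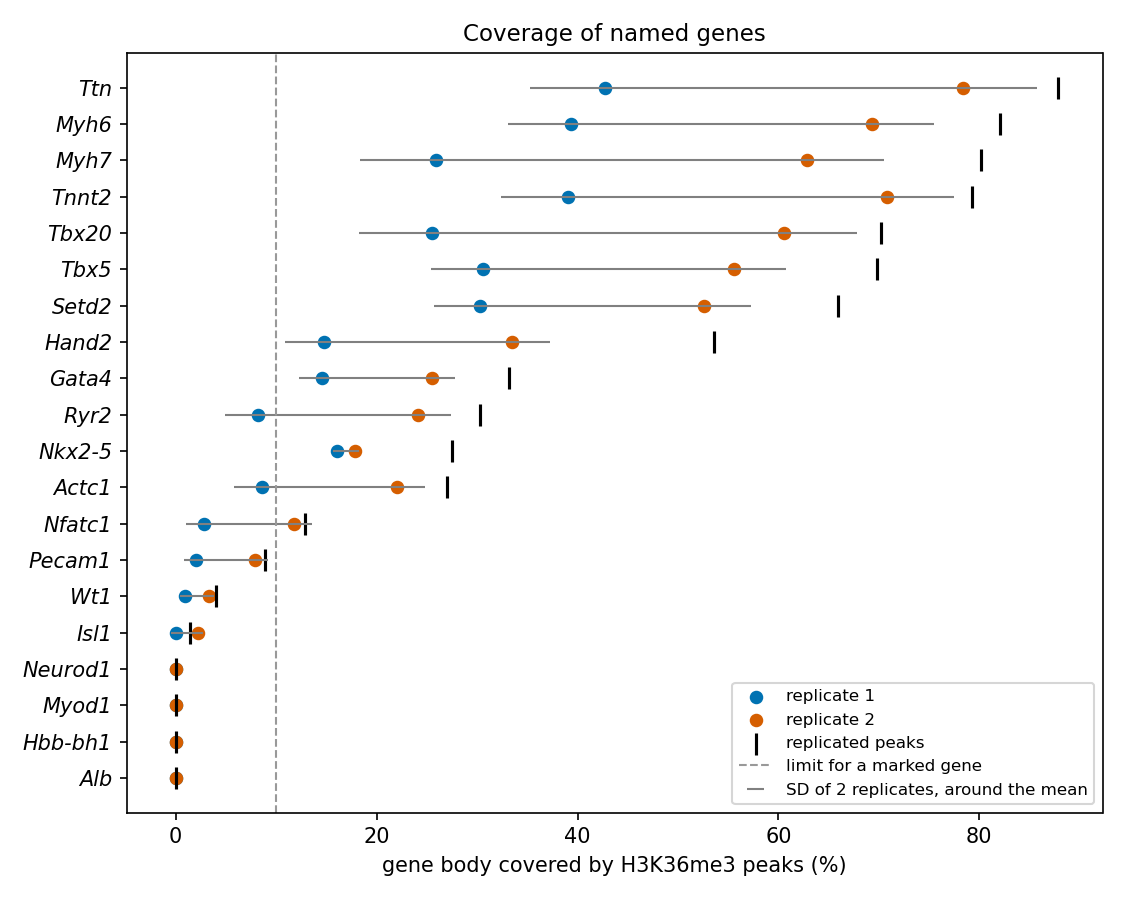
Percent of the gene body covered by H3K36me3 peaks (x axis, %) for the 20 genes fixed beforehand (y axis): points are the replicates, lines the SD of 2 replicates around their mean, black ticks the replicated list, and the dashed line the 10% limit. Ttn lies highest at 87.8%, and Hbb-bh1, Myod1, Alb and Neurod1 lie at 0.

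The first comparison was between the replicates. Of the peaks of replicate 1, 75.7% had at least 50% of their length covered by peaks of replicate 2, against a mean of 4.73% when one list was shifted along the chromosomes. Of the peaks of replicate 2, 24.3% were covered in this way by replicate 1, against 2.42% after shifting. The Jaccard index of covered bases was 0.417, against 0.0171. None of the 100 shifts reached any of these values (permutation by shifting, p = 0.0099, the smallest the shifts can give). Shifting also moves peaks off genes: for replicated peaks, 52.3% of bases lay outside annotated genes after shifting, against 4.38% observed. The shifts therefore do not separate agreement of the replicates from a shared placement over genes. With at least 1 shared base the shares were 84.8% and 43.0%, and with 50% of both peaks shared they were 20.1% and 14.6%, so the rule for sharing sets the value.

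Of 21911 protein-coding genes, 9001 (41.1%) were marked by replicated peaks. The replicates' own lists marked 6591 (30.1%) and 8647 (39.5%), a mean of 34.8% ± 6.64 (SD, n = 2). Both lists marked 6566 genes, while 25 were marked in replicate 1 alone and 2081 in replicate 2 alone. Across genes, which are not independent replicates, Spearman's rho of the percent covered was 0.948. It included genes without a covered base, since 12127 genes had one in replicate 1 and 13181 in replicate 2. In genes marked in both, the median ratio of the percent covered in replicate 2 to that in replicate 1 was 1.62. Shifting the replicated peaks along the chromosomes gave a mean of 2890 marked genes, with 3116 as the highest of 100 shifts. Marked genes made up 9.34% of genes under 2 kb, 53.5% of those of 20 to 50 kb and 13.1% of those of 200 kb or more (2.11% in replicate 1 and 11.6% in replicate 2).

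Among genes of 10 kb or more the largest coverage was that of 1700109H08Rik, at 96.8%. It was followed by Sf3b3 (a splicing factor subunit) at 95.5%, Trrap (a scaffold of histone acetyltransferase complexes) at 95.1%, Gpi1 (a glycolytic enzyme) at 95.1%, and Fn1 (fibronectin) at 94.5%. Rnf40, a ubiquitin ligase of histone H2B, was covered over 94.4%, Phykpl over 94.2%, the splicing factor gene Rbm39 over 94.2%, Mybpc3 (cardiac myosin-binding protein C) over 94.1% and Rbm5 over 94.0%. In replicate 1 these 10 genes ranged down to 61.2% (Rbm39), and in replicate 2 down to 84.0% (Rbm39).

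Gene lists of the heart differed in how many members were marked. Of 26 sarcomere and contractile genes, 24 were marked, 19 in replicate 1 and 24 in replicate 2 (log2 odds ratio 3.82, Fisher's exact test, adjusted p = 1.82e-07). Mybpc3 (94.1%), Ttn (87.8%) and Myh6 (82.0%) had the largest coverage. Tcap had 0% under replicated peaks although the replicates' own lists gave 28.2% and 8.22%, and the X-linked Smpx had 2.73%. Of 26 cardiac transcription factor genes, 19 were marked (log2 odds ratio 1.90, exact adjusted p = 0.00184), led by Gata6 (75.1%), Gata5 (74.5%) and Tbx20 (70.2%), while Hey1 and Pitx2 had 0%. In replicate 1 alone 12 of these 26 were marked, and the exact adjusted p was 0.109.

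Calcium handling and ion channel genes were marked in 12 of 22 cases, 8 in replicate 1 and 12 in replicate 2, and did not pass the test (log2 odds ratio 0.77, Fisher's exact test, adjusted p = 0.223). Atp2a2, the calcium pump of the sarcoplasmic reticulum, was covered over 93.0%, Kcnh2 over 61.4% and the sodium channel gene Scn5a over 50.2%, whereas Hcn1 and Kcnj3 had 0%. These genes were long (median 129 kb), and their median coverage of 13.7% lay above 97.9% of the random lists matched on gene length. The pooled list marked 15 of the 22, with an exact adjusted p of 0.0388, and with a 5% limit it was 0.0414. Of 22 endocardial and endothelial genes, 11 were marked (log2 odds ratio 0.52, exact adjusted p = 0.410), among them Egfl7 (39.0%), Eng (35.3%) and the receptor gene Kdr (34.9%), and Cldn5 and Emcn had 0%. Here the lists went apart: replicate 1 marked 1 of the 22, below other genes (log2 odds ratio −2.63, exact adjusted p = 0.0128), and replicate 2 marked 9. The pooled list marked 16, above other genes (log2 odds ratio 1.67, exact adjusted p = 0.0120).

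Cushion mesenchyme and matrix genes were marked in 12 of 22 cases (log2 odds ratio 0.77, Fisher's exact test, adjusted p = 0.223), with Fn1 at 94.5%, Vcan (versican) at 61.0% and Pdgfra at 55.5%, and Msx1 and Msx2 at 0%. Epicardial and proepicardial genes were marked in 6 of 15 cases (log2 odds ratio −0.03, exact adjusted p = 1.00). Krt18 (59.1%), Podxl (28.9%) and Krt8 (24.1%) led this list, and Aldh1a2 and Msln had 0%. Second heart field and outflow genes were marked in 4 of 18 cases (log2 odds ratio −1.17, exact adjusted p = 0.187), including the Hedgehog receptor gene Ptch1 (62.8%), Wnt5a (43.8%) and Wnt11 (34.2%), while Eya1 and Fgf10 had 0%. Replicate 1 marked 6 cushion genes (log2 odds ratio −0.13), 2 epicardial genes (−1.22) and 3 second heart field genes, and replicate 2 marked 11, 4 and 4. None of these 3 lists passed the test in either replicate alone.

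Genes of other cell types were marked less often than other genes in 6 of the 7 lists tested. No liver gene of 21 was marked (log2 odds ratio −4.91, Fisher's exact test, adjusted p = 3.81e-05), with Hnf1a highest at 5.39%, then Serpinc1 at 3.56% and F2 at 2.01%, and with Afp and Ahsg at 0%. Skeletal muscle genes were marked in 1 of 21 cases (log2 odds ratio −3.25, exact adjusted p = 0.000785): Acta1 had 11.5% (0% in replicate 1 and 13.6% in replicate 2), Actn3 7.04% and Myl1 2.62%, and Chrna1 and Chrnd had 0%. Of 25 neuronal genes, 2 were marked (log2 odds ratio −2.71, exact adjusted p = 0.000685), namely Camk2a (18.28%) and Slc17a7 (13.1%), with 6.07% and 5.02% in replicate 1, which marked 0 of the 25. Syt1 came next at 0.122%, and Elavl4 and Gabra1 had 0%.

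Of 16 neural crest genes, 1 was marked (log2 odds ratio −2.85, Fisher's exact test, adjusted p = 0.00527). It was the neuregulin receptor gene Erbb3 at 17.5%; Ednrb had 2.79%, Plp1 1.26%, and Dlx5 and Foxd3 0%. Of 24 lymphoid and leukocyte genes, 3 were marked (log2 odds ratio −2.10, exact adjusted p = 0.00485): Cx3cr1 (25.3%), Foxp3 (13.9%) and Csf1r (10.7%), with Adgre1 and Cd19 at 0%. The only marked gene among 18 gut and pharyngeal endoderm genes (log2 odds ratio −3.03, exact adjusted p = 0.00197) was Gata4, at 33.2%, which is also a cardiac transcription factor; Vil1 had 8.57%, and Cdh1 and Cdx1 had 0%. Primitive erythroid genes were marked in 4 of 20 cases and did not pass the test (log2 odds ratio −1.36, exact adjusted p = 0.0899). Tfrc, the transferrin receptor gene, had 78.0%, Alas2 14.0% and Tal1 13.9%, and Gata1 and Gypa had 0%. Replicate 1 marked 0 neural crest, 1 lymphoid, 1 endoderm and 2 erythroid genes, and replicate 2 marked 1, 2, 1 and 3. With a marking limit of 20% only 1 of the 20 was marked, and the exact adjusted p was 0.00555.

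Metabolic and housekeeping genes were marked more often than other genes. All 26 cell cycle genes were marked in both replicates (log2 odds ratio 6.25, Fisher's exact test, adjusted p = 3.65e-10), from Bub1b (92.6%), Top2a (92.1%) and Mcm2 (91.9%) to Rrm2 (60.8%) and Pcna (51.9%). Of 83 ribosomal protein genes, 76 were marked (log2 odds ratio 3.88, exact adjusted p = 2.9e-21), with Rps15a (90.2%), Rps28 (84.3%) and Rpl26 (84.1%) highest and the gene copies Rpl10l and Rpl39l at 0%. Of 81 oxidative phosphorylation genes, 73 were marked (log2 odds ratio 3.64, exact adjusted p = 1.58e-19), led by Atp5b (89.3%), Uqcrc2 (87.3%) and Ndufa10 (86.5%), and Atp5k and Atp5s had 0%. Proteasome genes were marked in 33 of 39 cases (log2 odds ratio 2.89, exact adjusted p = 9.0e-08). Psmc4 (88.9%), Psmc1 (86.4%) and Psmc6 (84.7%) were highest, and Psma8 and Psmb10 had 0%.

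Glycolysis genes were marked in 19 of 21 cases (log2 odds ratio 3.49, Fisher's exact test, adjusted p = 7.87e-06), with Gpi1 (95.1%), the glucose transporter gene Slc2a1 (89.5%) and Pkm (85.6%) highest, and Slc2a3 (7.25%) and Eno2 (0%) unmarked. Fatty acid oxidation genes were marked in 18 of 21 cases (log2 odds ratio 2.92, exact adjusted p = 9.35e-05). Cpt1b, the muscle form of carnitine palmitoyltransferase, had 88.1%, Acadvl 77.5% and Hadha 77.4%, whereas Cd36 had 0.307% and Ppara 0%.

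Of 31 genes of the Notch, BMP and TGF-beta pathways, 26 were marked (log2 odds ratio 2.79, Fisher's exact test, adjusted p = 3.13e-06), including Notch3 (73.5%), Jag1 (66.7%) and Smad6 (65.4%); Rbpj had 3.23% and Bmp5 2.43%. Replicate 1 marked 13 of the 31 (exact adjusted p = 0.205) and replicate 2 marked 25. Genes of the Wnt, FGF, neuregulin and retinoic acid pathways were marked in 17 of 32 cases (log2 odds ratio 0.70, exact adjusted p = 0.223), 12 in replicate 1 and 15 in replicate 2. The pathway lists were not tested against each other. Erbb2, the neuregulin co-receptor gene, had 82.2%, Axin2 59.98% and Lrp5 52.3%, and Aldh1a2 and Cyp26a1 had 0%.

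Among chromatin lists, genes that write, erase or read H3K36 methylation were marked in 23 of 25 cases (log2 odds ratio 3.76, Fisher's exact test, adjusted p = 3.72e-07), with Kdm4a at 90.5%, Psip1 at 81.6%, Brpf1 at 81.0%, Kdm4c at 9.53% and Phf19 at 7.64%. Of 391 Zfp genes, which encode zinc-finger proteins, 285 were marked (log2 odds ratio 1.98, exact adjusted p = 1.4e-36), from Zfp869 (100%), Zfp207 (92.5%) and Zfp335 (91.5%) to Zfp114 and Zfp174 (0%). Imprinted genes were marked in 14 of 25 cases (log2 odds ratio 0.86, exact adjusted p = 0.187), with Igf2r at 93.8%, Nnat at 82.6% and Peg3 at 73.1%, and Ascl2 and Dcn at 0%. No gene was marked among 67 replication-dependent histone genes (log2 odds ratio −6.56, exact adjusted p = 2.5e-15), where Hist3h2a had 4.47% and Hist1h1a and Hist1h1b 0%. The same held for 39 Hox cluster genes (log2 odds ratio −5.79, exact adjusted p = 5.01e-09), where Hoxb3 had 0.971% and Hoxa1 and Hoxa10 0%. None of 1134 olfactory receptor genes, such as Olfr1 and Olfr10, was marked (log2 odds ratio −10.76, exact adjusted p = 4.62e-269), nor was any of 326 vomeronasal receptor genes, such as Vmn1r1 and Vmn1r10 (log2 odds ratio −8.87, adjusted p = 3.78e-75).

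Over the 29 lists, 11 were marked more often than other genes, 10 less often and 8 did not pass the test. Median coverage lay above at least 96.8% of the random lists matched on gene length for each of the 11 lists marked more often. The same was true of the calcium handling list (97.9%), which did not pass the test. For most lists marked less often that percentile said little, since the matched medians were also at or near 0, and the number of marked members was compared with the matched lists in addition, a choice made after seeing the data. The matched lists held 13.3 marked genes on average against 0 for the Hox genes and 7.07 against 0 for the histone genes.

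**Figure D2:**
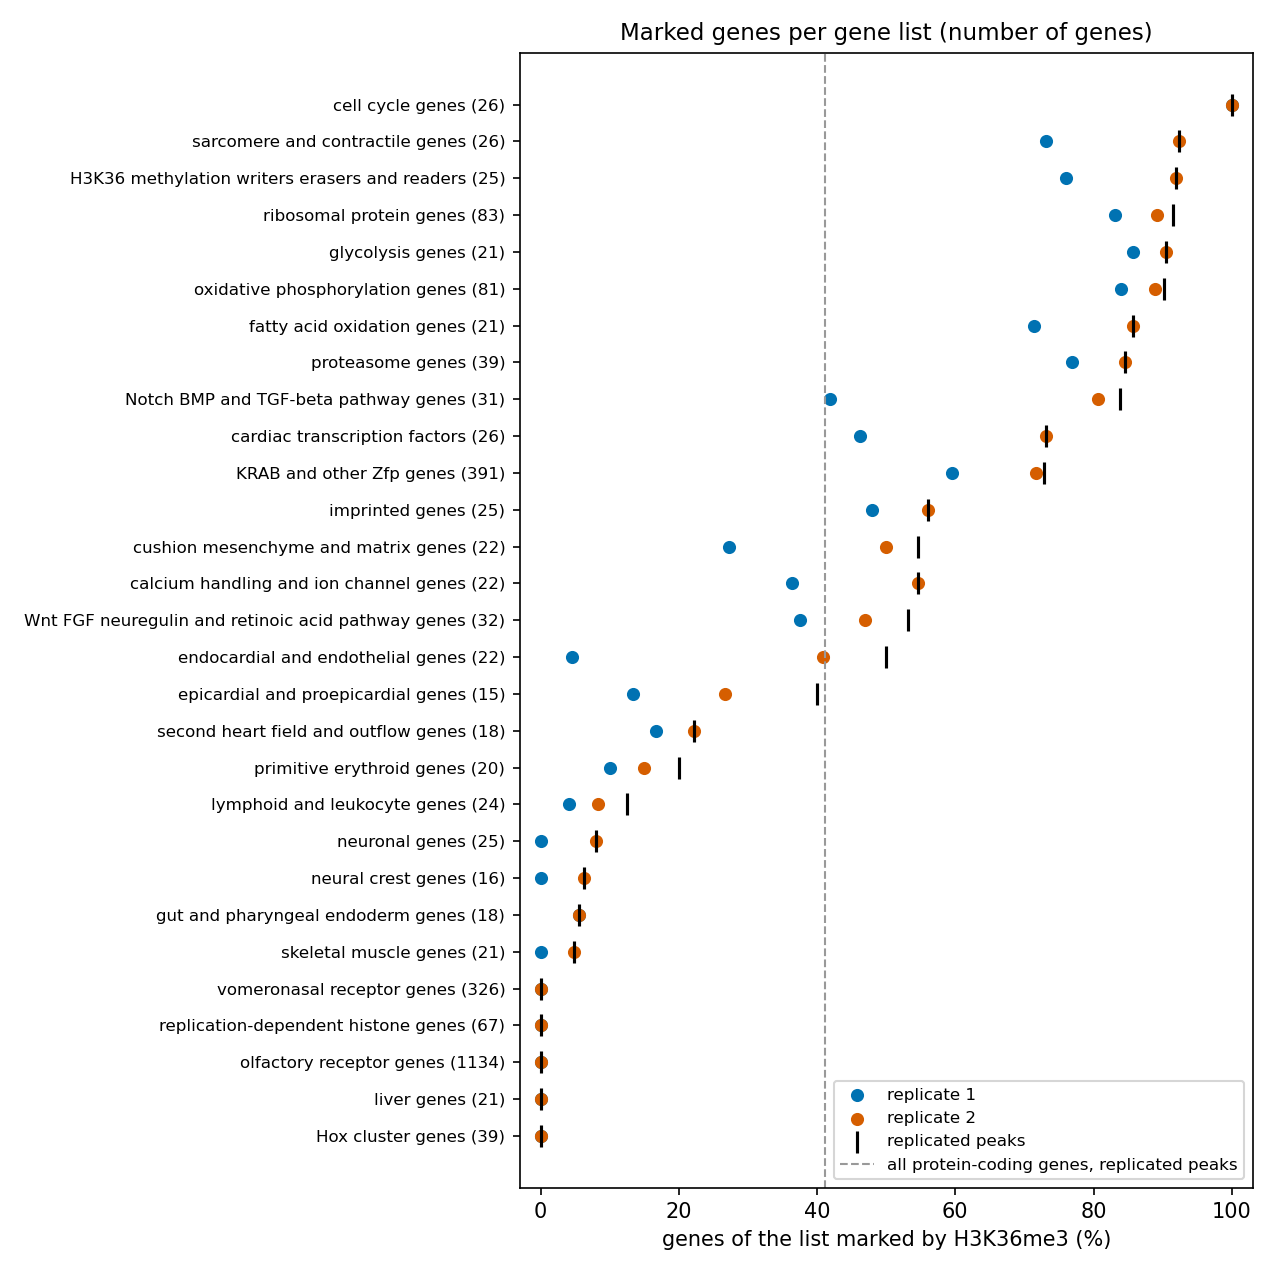
Percent of each list's genes marked by H3K36me3 (x axis, %) for 29 gene lists with their sizes (y axis): points are the replicates' own lists, black ticks the replicated list, and the dashed line all protein-coding genes at 41.1%. Cell cycle genes lie at 100% in both replicates, and endocardial and endothelial genes show 1 of 22 in replicate 1 against 9 in replicate 2.

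Coverage rose from the start of genes towards their end. In 6773 marked genes of 10 kb or more, replicated peaks covered 8.98% of the bases in the first of 10 bins and 65.7% in bin 9, with 63.9% in bin 10. The last 2 bins averaged 64.8% and the first 2 bins 18.9%, a ratio of 3.42. Over the replicates' own lists, in the same genes, the ratio was 3.94 ± 0.436 (SD, n = 2). The last 2 bins were higher in 89.3% of the genes and lower in 9.61%. No test was made over the 2 replicates.

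**Figure D3:**
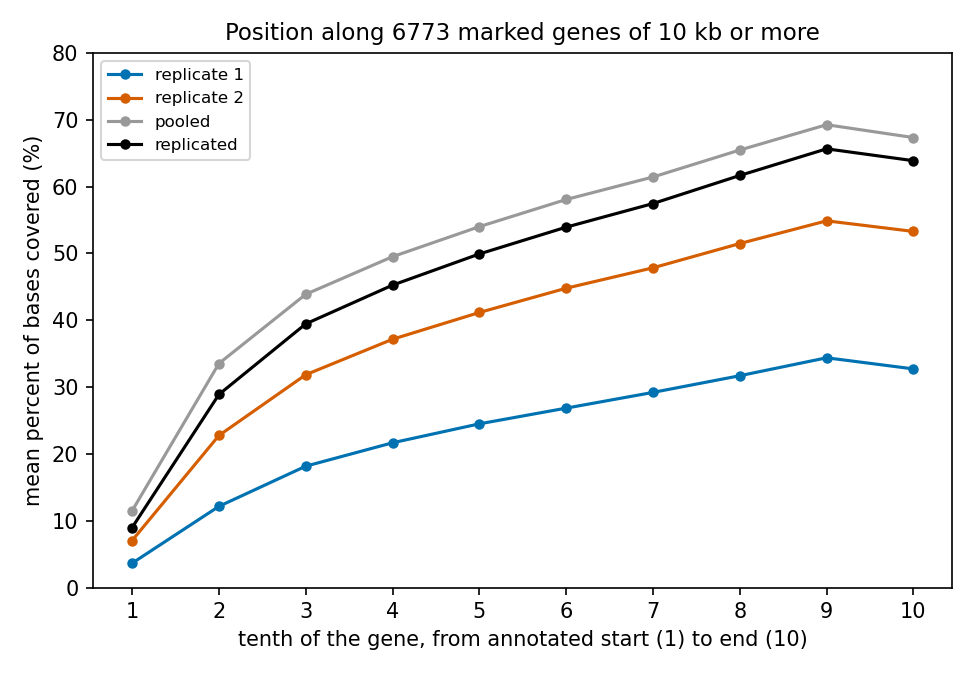
Mean percent of bases covered by H3K36me3 peaks (y axis, %) in 10 equal bins from annotated start to end (x axis) of 6773 marked genes of 10 kb or more, with a line for each peak list. The replicated list goes from 8.98% in bin 1 to 65.7% in bin 9, and replicate 1 lies lowest in each bin.

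Summed over genes, exonic bases were covered more than intronic bases. In 8858 marked genes with several exons, 61.7% of exonic and 35.5% of intronic bases lay under replicated peaks, a ratio of 1.74. Replicate 1 alone gave 33.7% and 15.2%, and replicate 2 gave 52.5% and 28.6%. The replicates' own lists gave a ratio of 2.03 ± 0.267 (SD, n = 2). The ratio was not computed within genes or by position, so gene length and position along the gene were not separated from exon status. By bases, 72.4% of the replicated peaks lay in introns, 2.01 times the mean of shifted peaks, and 21.9% in exons, 6.46 times that mean. Regions within 1 kb of a gene start held 0.418% of peak bases against 1.60% after shifting. Other annotated genes held 0.940% against 6.70%, and sequence outside annotated genes held 4.38% against 52.3%. Across the replicates' own lists, exons held 24.4% ± 2.58 and introns 69.9% ± 2.13 (SD, n = 2).

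Genes on chromosome X were marked less often than those on autosomes. Of 948 X-linked genes, 166 (17.5%) were marked, against 8835 of 20780 autosomal genes (42.5%; log2 odds ratio −1.80, two-sided Fisher's exact test, p = 2.85e-58). The lowest autosome was chromosome 14, at 34.0%, and the highest chromosome 8, at 51.9%. None of 183 genes on chromosome Y was marked. Both replicates showed the direction: 5.91% on X against 31.4% in replicate 1 (log2 odds ratio −2.86), and 15.8% against 40.9% in replicate 2 (log2 odds ratio −1.88). Both pools mixed male and female embryos, and the sex ratio of either was not given.

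**Figure D4:**
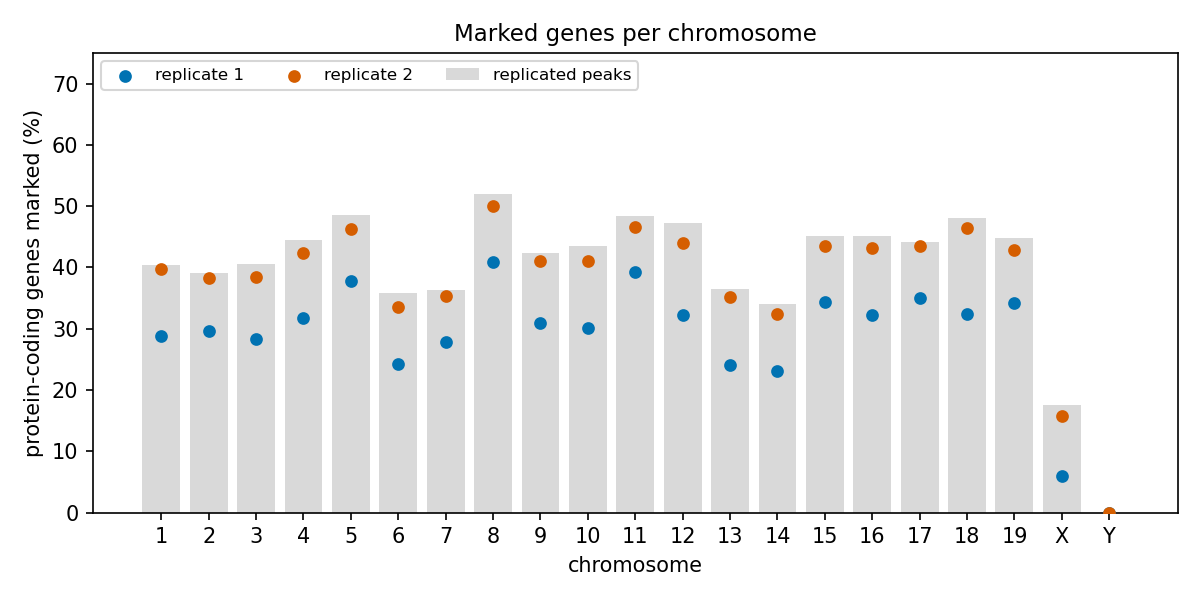
Percent of protein-coding genes marked by H3K36me3 (y axis, %) on each chromosome (x axis), with bars for the replicated list and points for the replicates' own lists. Chromosome X stands at 17.5%, below the lowest autosome, chromosome 14, at 34.0%.

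Replicated peaks formed 20189 domains with a median length of 4.20 kb, of which 855 were 50 kb or longer and 89 were 100 kb or longer. The longest ran over 277 kb of chromosome 2, from 76678697 to 76955311, across parts of Ttn and Plekha3, and 88.9% of it was covered (43.5% in replicate 1 and 78.9% in replicate 2). Among the next were domains of 201 kb within Ryr2 (chromosome 13, 11634058 to 11835205), 179 kb over Myo18b, an unconventional myosin gene (chromosome 5, 112701081 to 112879615), and 170 kb within the calcium channel gene Cacna1c (chromosome 6, 118590716 to 118760701). In replicate 1 the Ryr2 and Cacna1c domains were covered over 14.5% and 14.3%. A domain of 206 kb on chromosome 14 (31006707 to 31213047) joined 8 genes, Glt8d1, Gnl3, Pbrm1, Smim4, Nt5dc2, Stab1, Nisch and the cardiac troponin C gene Tnnc1. The rest of the 10 longest lay over Eif4g3 (215 kb), Fbn2 (fibrillin 2, 202 kb), Syne2 (201 kb), Usp34 with Ahsa2 (176 kb) and Ttc19 with Ncor1 (171 kb). With a merging gap of 1 kb the longest domain was 115 kb, so these lengths depend on the gap.

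**Figure D5:**
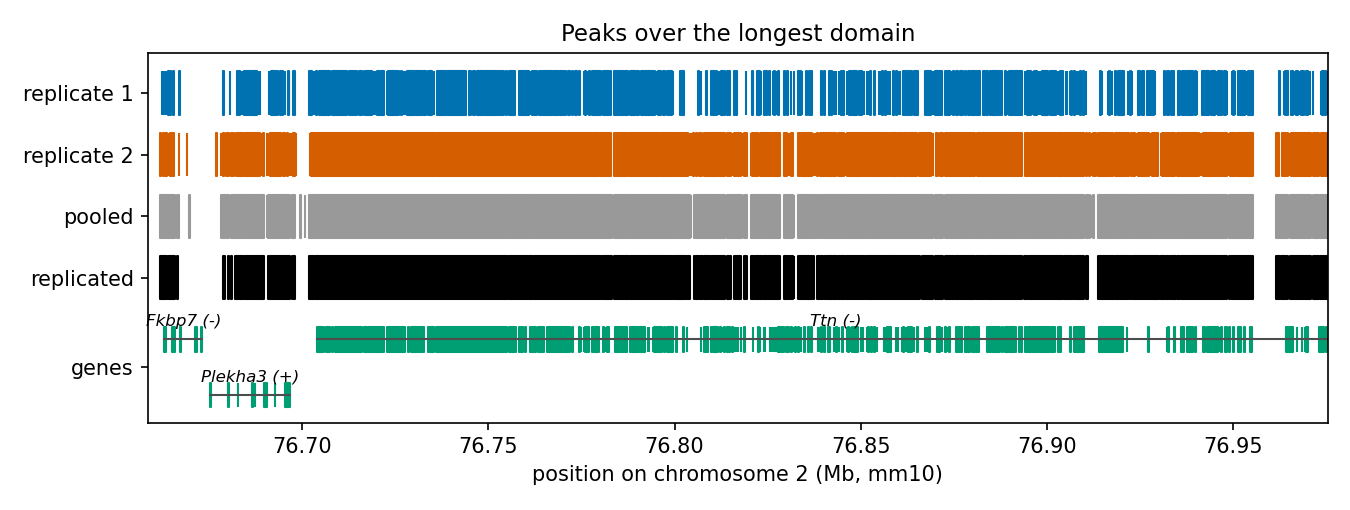
Peaks of the 4 lists (upper rows, a bar per merged peak) and exons of annotated genes with their strand (lower rows) against position on chromosome 2 (x axis, Mb, mm10) around the longest domain. Peaks cover Ttn along 87.8% of its body in the replicated list, with more gaps in replicate 1 (42.7% covered).

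Outside annotated genes lay 834 domains, 5 of them of 10 kb or more. The longest was 23.1 kb on chromosome 17 (17185117 to 17208239), 38.3 kb from Zfp97. It was followed by 15.3 kb on chromosome 5 (104573803 to 104589102), 11.7 kb on chromosome 5 (122531511 to 122543255), 6.95 kb from Ift81, and 11.1 kb on chromosome 12 (108773127 to 108784220), 8.75 kb from Yy1. A domain of 10.4 kb on chromosome 6 (8245532 to 8255916) lay 0.019 kb from Rpa3. The others were 8.10 kb on chromosome Y (90737791 to 90745889), 7.46 kb on chromosome 2 (181294851 to 181302312), 7.30 kb on chromosome 17 (3069039 to 3076334), 6.89 kb on chromosome 11 (69372810 to 69379696) and 6.87 kb on chromosome 5 (119808840 to 119815710). The last lay 17.0 kb from Tbx5.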

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

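Signals outside protein-coding genes were listed for a closer look when their count exceeded 3, the limit that a count of 0 allows. This limit is not a test against chance, and no chance value was computed for the counts. By bases, sequence outside annotated genes held less of the replicated peaks than after shifting (4.38% against 52.3%), and so did other annotated genes (0.940% against 6.70%). Of 5358 lincRNA genes that overlapped no protein-coding gene, 104 (1.94%) were marked, with 0.896% in replicate 1 and 1.72% in replicate 2. No minimum distance was set, so peaks reaching over from a neighbouring gene were not removed. Those of 10 kb or more with the largest coverage, chosen after their values were seen, included 1700020I14Rik (77.7%) and the neighbouring maternally expressed genes Mirg (75.4%) and Meg3 (71.4%) of chromosome 12. Domains of 10 kb or more outside annotated genes numbered 5. On scaffolds outside the chromosomes lay 5 replicated peaks, one of which, 5666 bp long on scaffold 4_GL456216_random, had a −log10 p of 152 and ranked 3 among all 137455. No explanation was tested for these 3 signals.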

How the results depend on the processing

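The test against length-matched lists was chosen after the result was seen, and all other alternatives were fixed before the data were examined. Of 404 alternative values of the main results, 371 were counted as unchanged. For gene lists and chromosome X, only the sign and the call were compared, not the size. The other results were compared by size within set bounds. Among the 371 were 5 of uncalled lists whose sign turned without a call (endocardial genes at −0.70 with −log10 q of at least 5 and −0.78 with a 20% limit, cushion genes at −0.13 without replicate 2, epicardial genes at 0.24 without overlapping genes and 0.01 against length-matched lists). Of the rest, 23 moved in size beyond the set bounds, 7 gained a call, 2 lost one and 1 reversed. Of the 21 lists that passed the test, 19 kept their call in all 11 alternatives. The X-linked deficit stayed between −2.86 and −1.62 (log2 odds ratio), and marked genes numbered 6304 to 9879. Without replicate 2, the call was lost for cardiac transcription factors (log2 odds ratio 1.00, with 2.00 without replicate 1; adjusted p = 0.109, Fisher's exact test) and for Notch, BMP and TGF-beta genes (0.76, with 2.59 without replicate 1; adjusted p = 0.205). Endocardial and endothelial genes turned to −2.63 without replicate 2 and stood at 0.11 without replicate 1; they passed the test at 1.67 with the pooled list and at 1.33 with a 5% limit. Calcium handling genes passed at 1.37 with the pooled list and at 1.33 with the 5% limit. Erythroid genes passed at −1.67 with −log10 q of at least 5, at −2.81 with a 20% limit and at −1.71 without replicate 1, but not without replicate 2 (−1.67, exact adjusted p = 0.0722). Between replicates left out, the ratio of last to first bins ranged from 3.63 to 4.25 and the exon to intron ratio from 1.84 to 2.22. Over the same pair of lists, peak bases near gene starts ranged from 0.435% to 0.535%, in exons from 22.6% to 26.3%, in introns from 68.4% to 71.4% and in other genes from 0.817% to 0.984%. The bin ratio was 2.81 in genes of 30 kb or more. With the pooled list, 0.510% of bases lay near gene starts, 1.08% in other genes and 4.88% outside genes. Peak sharing was 84.8% and 43.0% (replicate 1 in 2, and 2 in 1) with 1 shared base, 20.1% and 14.6% with 50% of both peaks, 80.5% and 22.4% with −log10 q of at least 2, and 71.7% and 30.01% with lists of equal length. The Jaccard index was 0.39996 with the limit on q and 0.444 with equal lengths. A gap of 1 kb gave 46312 domains with a longest of 115 kb, which follows from bridging shorter gaps, and 180706 peaks of replicate 1 passed a −log10 q of 2. Apart from the gap, the cause was not tested. Named genes kept their side of the 10% limit with the pooled list in 152 of 156 cases, in 154 without replicate 1 and in 141 without replicate 2, where Actc1 (8.58%), Ryr2 (8.21%) and Nfatc1 (2.84%) fell below it. Most of these genes were named for the largest or smallest coverage of their list by replicated peaks. The counts therefore say little about genes near the limit. Of 780 alternative values of single genes, 184 moved by more than the spread. No paired analysis was possible because there was 1 group. Depth was not given, so genes of low coverage cannot be called unmarked beyond these lists.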

Other observations

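Tests chosen only after the result was seen were the sarcomere list against the other heart lists and the erythroid list, calcium handling genes included, Zfp genes among the strongest peaks, and marked counts against lists matched on gene length. The tests of X-linked housekeeping genes and of the change in rank between replicates were also not fixed before the data were examined. They were set up for patterns already seen. The change in rank was first run with 1000 random lists and then with 10000, and its form with lists matched on gene length was added after the first result. The tests of X detection, detection in replicate 1, endothelial share and heart lists were read as open only after their values were seen. Zfp genes stood out among the strongest peaks: of the 100 replicated peaks with the largest −log10 p, 30 lay over Zfp genes, as did 99 of the 1000 strongest, against 1.90% of all replicated peaks. Any shared base counted, and peaks were not matched on length, so longer peaks had more room to meet a gene. The genes under the 15 strongest, named after their values were seen, included Zfp354c, Zfp146, Zfp68 and Zfp777 beside Spred2, an inhibitor of growth factor signalling. In marked Zfp genes with several exons, 66.3% of exonic and 35.5% of intronic bases were covered (284 genes), against 61.6% and 35.5% in other marked genes (8574 genes).

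Sarcomere genes were marked more often than 4 other lists of heart genes and than primitive erythroid genes. Against 24 of 26 sarcomere genes stood 11 of 22 endocardial genes (adjusted p = 0.00365, two-sided Fisher's exact tests over 6 lists), 12 of 22 cushion genes (adjusted p = 0.00704), 6 of 15 epicardial genes (adjusted p = 0.00108), 4 of 18 second heart field genes (adjusted p = 7.31e-06) and 4 of 20 erythroid genes (adjusted p = 6.74e-06). The difference from 19 of 26 cardiac transcription factors did not pass (exact adjusted p = 0.140). Calcium handling and ion channel genes, also used by heart muscle, were marked in 12 of 22 cases, less often than sarcomere genes (two-sided Fisher's exact test outside that family, p = 0.00587), but they are longer (median 129 kb against 24.5 kb), held more marked genes than the mean of 7.66 in lists matched on length, and gene length was not accounted for in any of these tests. Whether genes used in fewer cells leave a weaker mark in whole-heart chromatin stays open: the largest of the 5 adjusted p values, 0.00704, shows a difference between lists but not its source, and cell shares were not measured.

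Chromosome X had fewer marked genes than autosomes, and 2 explanations were weighed. If the X only held more tissue-restricted genes, X-linked members of 6 housekeeping lists should have been covered like autosomal ones, but the 9 X-linked members, among them Pgk1 (61.2%), Rps4x (54.8%) and Ndufa1 (0%), averaged 24.6% ± 23.8 (SD over genes) against 57.1% ± 24.6 for 262 autosomal members. In the replicated list the difference of −32.51 percentage points (permutation test, p = 0.00054) argues against gene content as the whole cause. The X-linked members held no cell cycle or fatty acid oxidation gene, unlike the autosomal ones, and the test matched neither list nor gene length. The means depended on the list, at 4.51% against 35.4% in replicate 1 and 20.6% against 48.8% in replicate 2. Lower detection of a chromosome present in fewer copies could not be excluded: in the pooled list the X-linked members lay −5.67 percentage points from the autosomal members in replicate 1 alone (permutation test, p = 0.418), and 9 genes are too few to decide. A single active X in female cells also stays open, untested because the sexes were pooled.

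Endocardial and endothelial genes went from 1 of 22 marked in replicate 1 to 9 in replicate 2, while the pooled list marked 16. The list's median rank was −4.47 percentile points lower in replicate 1 than in replicate 2. This lay at percentile 0.01 of 10000 random lists matched on coverage and at percentile 0 of lists matched on coverage and gene length. The list was picked for its low count of marked genes in replicate 1. The test used the same coverage values and was not adjusted over the lists. It therefore cannot decide whether lower detection of genes of intermediate coverage or of long genes was the whole cause. The sarcomere list (−2.76 points, percentile 0.02), the calcium handling list (−2.08, percentile 0.43), the fatty acid oxidation list (−2.51, percentile 0.5) and the cushion list (−1.10, percentile 1.62) were also lower in replicate 1. Genes without a peak in either list moved by 2.41 by construction, and the ribosomal (2.54, percentile 100), Zfp (1.23, percentile 99.8), glycolysis (1.61, percentile 99.1) and Wnt and FGF lists (2.49, percentile 99.98) lay above their matched lists, the last by little more than that shift. A smaller share of endothelial chromatin in the pool of replicate 1 cannot be told apart from a wider difference between the pools or in the further files named for each list, since the muscle list moved the same way; no biological explanation could be tested within 1 group.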
